A study of Homo sapiens with 6 samples.

How the data were processed

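Total RNA of sparse and confluent cultures of the human breast cell line MCF10 (MCF10A in the design text of the series), grown in DMEM with 10% fetal bovine serum, was isolated with a silica-column kit and hybridised to 2-colour cDNA arrays at 42 °C for 15 h, per the labels' protocols. Each of 6 arrays carried both cultures. The title numbers 1, 2 and 3 each occur on an array with confluent RNA in channel 1 and on an array marked R with sparse RNA in channel 1. By the dye labels the confluent RNA was on Cy5 on array 1 alone. The title of the series speaks of genes related to the epithelial-mesenchymal transition.

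The values are log ratios of the channels of each array, processed by the authors before they were deposited, and are read here as log2. The base is inferred, because values from -11.78 to 10.29 fit a 16-bit scanner on a log2 scale and not on a log10 scale; a natural logarithm is not strictly ruled out. The image software, background correction, normalization method, rule for missing values and numerator channel are not given in the sources used here. Medians per array lay between -0.0022 and 0.016, so the deposited columns were already centred. Per array 24170 to 25774 of 27648 spots had a value and 6.78 to 12.58% had none, and signal over background was not analysed here. Adjacent spots carried the same clone in 9071 of 9071 pairs with an accession, correlated at 0.954 to 0.993 and differed with an SD of 0.085 to 0.149.

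Probes were named from the platform annotation table: 17488 probes had 1 gene symbol, 654 had several and 9506 had none. Of the 17488, 17450 were found by Entrez ID in the RefSeq table, and 0 symbols needed updating. Probes with none or several symbols were kept as their own features and not named. Spots of a gene were averaged within an array, giving 6043 genes, of which 1172 had more than 1 clone. Where clones of a named gene differ in sign, which held for 4 of 135 named genes, the text gives this for the genes it prints. cDNA clones can bind transcripts of close paralogs.

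The direction of each column was decided by a rule fixed before the data were examined, for the whole table and not array by array: of the readings channel 1 over channel 2, Cy5 over Cy3 and all columns already turned the same way, the one with the highest lowest pairwise correlation was used. All columns running the same way had a lowest r of 0.662 and was taken, which by the same rule leaves the numerator culture unknown. Each array was then centred on its median. Features with a value on at least 4 arrays and in all 3 numbers were tested, in total 5759 genes and 9273 unnamed probes.

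Arrays with the same title number were averaged, giving n = 3, because the labels do not say whether they share RNA extracts. The mean log2 ratio was tested against 0 with lmFit and eBayes of limma 3.58.1 (statmod 1.5.0, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all genes and unnamed probes. A gene was called at an adjusted p under 0.05. The words higher and lower are used of called genes. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 28 lists, and with an estimated correlation and fry as alternatives. With an estimated correlation camera has only the few degrees of freedom that n = 3 leaves, so it could hardly call any list. Counts adjusted over the list alone used the members of a list as the family of tests. The channel effect was the difference between arrays 1, 2 and 3 and arrays 1R, 2R and 3R in limma, each array as its own replicate. It took this form because the columns already ran the same way. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

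The 28 gene lists and the rule for named genes were fixed before the data were examined. The rule named the 10 called genes with the largest mean ratio each way and the same sign on every measured array, 28 genes chosen for their link to epithelial and mesenchymal states or to proliferation, of which 18 could be tested, and up to 4 called members of each list with the largest ratios. It named 135 genes, of which the text prints a part. Older symbols in the lists were matched to current ones, such as CCN2 and CCN1.

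The fit was tested on simulated data for this comparison with 3 independent replicates, 5469 genes and 200 changed genes. It recovered 62% of genes changed by 0.5 on the log2 scale and 92% of those changed by 1, with 100% of the recovered genes in the right direction and 3 false calls (1.9% of calls). That simulation assumes independent averages. A simulation of 20 draws without any change, with deviations shared within the closest pairs of arrays, gave an unadjusted p under 0.05 for 18.8% of genes when averaged by number and for 5.5% when averaged by closest pair, with a mean of 0.6 and 0 genes past an adjusted p of 0.05.

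Alternatives listed before the data were examined covered the replicate structure, a channel term, leaving out each number and each array, both other readings of the columns, centring, scaling and quantile normalization, the filter on missing values, a fit per probe, other thresholds, robust and unmoderated tests, and other set tests. Added after seeing the data were averages of the closest arrays, the closest pair as a random block, and a fit without arrays 1 and 3. Fits that left out 1 array took the remaining arrays as separate replicates. A call lost there can therefore also stem from the change from the 3 averages of the main fit.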

Results

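The cells were of the human breast line MCF10, as the sample labels give it, called MCF10A in the design text of the series, where MCF10A is a non-tumorigenic epithelial line. RNA from sparse cultures, grown to 10 to 20% confluence, and from confluent cultures, grown to 80 to 100% confluence, was hybridised together on 6 cDNA arrays with the dyes Cy3 and Cy5. The study used the contrast to look for genes linked to the epithelial-mesenchymal transition (EMT), the switch of epithelial cells to a mesenchymal state. Channel 1 held confluent RNA on arrays 1, 2 and 3 and sparse RNA on arrays 1R, 2R and 3R, while by dye the confluent RNA was on Cy5 on array 1 and on Cy3 on the other 5. Between 24170 and 25774 of 27648 spots had a value per array, and 5759 named genes could be tested. The number of arrays limits the precision. The labels do not say which arrays came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

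The arrays recorded closely related differences between the cultures. All 15 pairs of arrays correlated positively across probes as deposited, with Pearson r from 0.662 to 0.925 (probes are not independent replicates, and no test was made). Reading the columns as channel 1 over channel 2 would have made 9 pairs correlate below -0.3, with a lowest r of -0.896. Reading them as Cy5 over Cy3 would have made 5 pairs do so, with a lowest r of -0.925. The columns were therefore taken to run the same way already, and which culture is the numerator of the ratios is not settled. The terms numerator culture and denominator culture are used here for that reason, and every signed value turns if the inverse ratio was deposited. The labels of array 1 make the numerator the confluent culture under both of the rejected readings, whereas Cy5 over Cy3 on the other 5 arrays would make it the sparse culture. Arrays 1 and 3 were closest to each other (r = 0.925) and correlated with the other 4 at 0.662 to 0.714, while those 4 correlated among themselves at 0.828 to 0.898. Closest pairs were arrays 1 and 3, arrays 2 and 1R (r = 0.896), and arrays 2R and 3R (r = 0.898), so that the number in the title did not mark the most similar arrays.

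**Figure D1:**
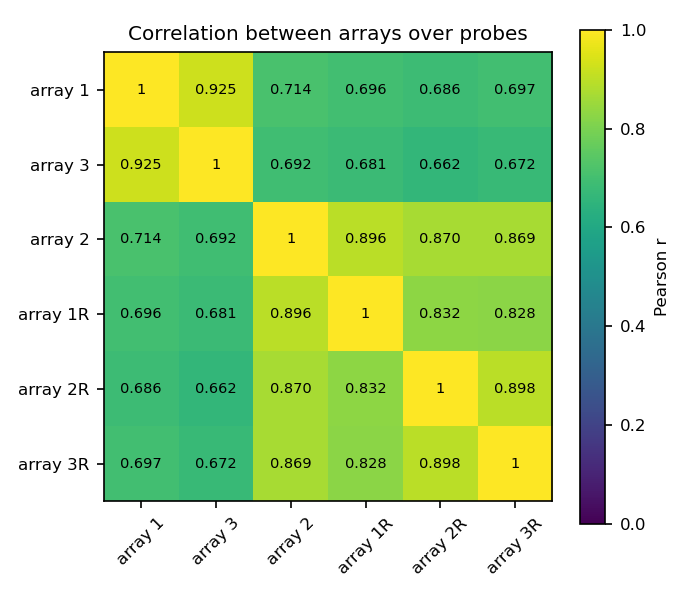
Pearson correlation between each pair of the 6 arrays over probes with a value on both, as deposited, with colour from 0 to 1. Arrays 1 and 3 form a pair at 0.925 and correlate with the other 4 arrays at 0.662 to 0.714.

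Ratios departed from 0 for a large share of the genes. By the dye labels the confluent RNA was on Cy5 on array 1 alone. On the other arrays a dye effect on single genes was therefore not separated from a difference between the cultures. The calls below may include such dye effects. If the dye labels are right, such an effect would have the opposite sign on array 1. It could then change the size of a ratio, but alone would not give the same sign on all 6 arrays. Of 5759 genes, 2637 had an adjusted p under 0.05 in the moderated limma test, 1364 higher and 1273 lower in the numerator culture, and 324 of them differed by 2-fold or more (183 higher and 141 lower). The same sign was seen on every measured array for 2401 of the 2637. Across all genes measured on 6 arrays, 2762 of 5469 (50.5%) had the same sign on each, against 3.125% for 6 independent signs and 12.3% in simulated data without change whose deviations were shared within the closest pairs. The simulated pairs were independent of one another. Any deviations shared between pairs would raise the 12.3%, which is therefore only a guide. Averaging the closest arrays instead of those with a shared number, an alternative chosen after seeing the data, left 1014 genes (585 higher and 429 lower), 1013 of them among the 2637. In the same simulated data an unadjusted p under 0.05 arose for 18.8% of genes when arrays were averaged by number and for 5.5% when averaged by closest pair. Unadjusted p-values by number are thus too small under that model, while the genes past an adjusted p of 0.05 averaged 0.6 by number and 0 by closest pair per simulated data set. No gene was changed in these simulated data, so only very small p-values could pass the adjustment. In the real limma fit many genes passed, and an unadjusted p of 0.0183 sufficed for CORO1A, of the blood and immune list. The 0.6 therefore does not give the number of false calls among the 2637.

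The highest ratios belonged to genes of several kinds. Values given as mean ± are log2 ratios of numerator over denominator culture, averaged over the 3 title numbers, with the SD over the 6 arrays unless another n is given. F3, the receptor that starts blood coagulation, stood at 3.02 ± 0.19 (an 8.10-fold difference), and SERPINE2, a secreted inhibitor of serine proteases, at 2.40 ± 0.86. Others were cell-cycle genes: PKMYT1, a kinase that inhibits CDK1, at 2.71 ± 0.68, RRM2, a subunit of ribonucleotide reductase, at 2.53 ± 0.80, CDC6, which loads the replicative helicase, at 2.36 ± 1.07, MKI67, the proliferation antigen Ki-67, at 2.33 ± 0.60, and ASF1B, a histone chaperone, at 2.28 ± 0.47. STEAP1, a membrane protein, reached 2.27 ± 0.59 and DTL, a substrate receptor of a ubiquitin ligase, 2.26 ± 1.31. AGAP1, a GTPase-activating protein of membrane traffic, had the highest mean, 3.39 ± 2.42 (SD, n = 5 arrays), but this rested on 7.90 on array 1 and was 2.58 without that array. Adjusted p for these 10 genes lay between 0.000278 (F3) and 0.00934 (AGAP1), and DTL lost its call with the closest arrays averaged (adjusted p = 0.0559).

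At the negative end, SRSF8, a splicing factor, had the lowest ratio of the genes with the same sign on every array, at -3.50 ± 0.66. TKT, transketolase of the pentose phosphate pathway, was at -3.39 ± 0.40, MAOA, the monoamine oxidase A, at -2.93 ± 0.51, and SELENOP, a secreted selenium carrier, at -2.80 ± 0.60. FOS and EGR1, transcription factors induced within minutes by growth factors, were at -2.62 ± 0.83 and -2.57 ± 1.60. PNRC1, a nuclear receptor coregulator, had -2.52 ± 0.48, TSC22D3, a glucocorticoid-induced leucine zipper protein, -2.49 ± 0.48, FXYD3, a regulator of the sodium pump, -2.48 ± 0.65, and MME, a cell surface peptidase of myoepithelial cells, -2.41 ± 0.21. Each had the same sign on all 6 arrays, with adjusted p between 0.000136 (TKT) and 0.00295 (EGR1). EGR1 lost its call with the closest arrays averaged (adjusted p = 0.0705), its ratio being -0.45 on array 1 and -0.57 on array 3 and between -3.78 and -3.40 on the other 4. A cDNA clone can bind transcripts of close paralogs, so SRSF8 in particular is uncertain as the source of its signal.

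**Figure D2:**
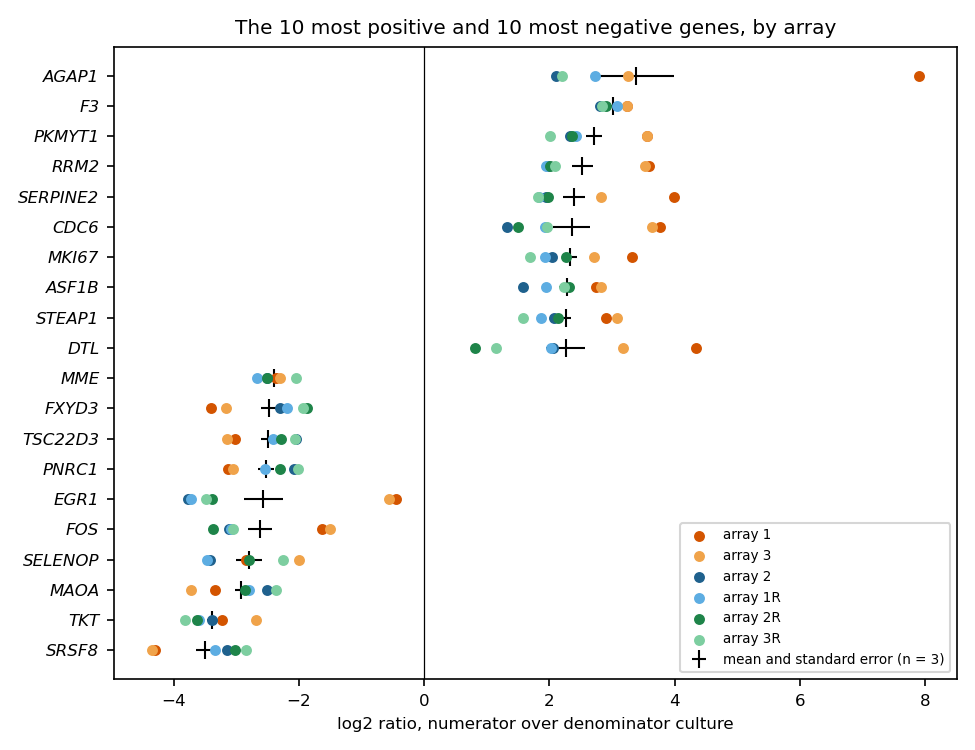
Log2 ratio of numerator over denominator culture on each array for the 10 most positive and the 10 most negative genes with the same sign on every measured array and an adjusted p under 0.05. Coloured points are arrays, vertical ticks the mean over the 3 title numbers and horizontal bars its standard error; AGAP1 on array 1, at 7.90, lies far from its other values.

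Genes of DNA replication and mitosis were higher in the numerator culture nearly as a block. Of 35 measured genes of the G1/S and DNA replication list, 33 were higher and 0 lower (33 and 0 adjusted over the list alone, and 30 and 0 with the closest arrays averaged), with a list mean of 1.07. Besides RRM2 and CDC6, these included UHRF1, which maintains DNA methylation at replication forks, at 1.89 ± 0.64, and PCNA, the sliding clamp of DNA polymerases, at 1.86 ± 0.50. The list of G2/M and mitosis had 36 of 38 genes higher and 1 lower (36 and 1 adjusted over the list alone, and 21 and 0 with the closest arrays averaged), with a mean of 1.31. MAD2L1, of the spindle checkpoint, stood at 2.00 ± 0.99, ANLN, a scaffold of the cleavage furrow, at 1.93 ± 0.93, and KIF23, a kinesin of the central spindle, at 1.90 ± 0.64. The lower gene was the kinase MELK at -0.20, named after its value was seen. Against all other genes both lists were shifted upwards in limma's camera test with a preset correlation (adjusted p = 2.24e-13 for G1/S and 1.17e-11 for G2/M). These calls did not hold with the correlation estimated from the 3 averages (adjusted p = 0.565 and adjusted p = 0.587 with an estimated correlation). That form of the test has few degrees of freedom with 3 averages and could hardly call any list. The same limit applies to the values with an estimated correlation given below. The mean of the G2/M list was 2.28 on array 1 and 1.98 on array 3, and 0.86 to 0.92 on the other 4. Without arrays 1 and 3, left out after seeing the data, the G2/M mean was 0.90 with 35 genes higher and 1 lower.

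Genes that restrain the cell cycle were more often lower than higher in the numerator culture. Of 19 measured cyclin-dependent kinase inhibitors and growth arrest genes, 11 were lower and 2 higher in the numerator culture (11 and 4 adjusted over the list alone, 8 and 0 with the closest arrays averaged), with a mean of -0.71. BTG1, an antiproliferative protein, stood at -1.96 ± 0.35, CDKN1C, the cyclin-dependent kinase inhibitor p57, at -1.94 ± 0.13, PDCD4, an inhibitor of translation initiation, at -1.91 ± 0.16, and GAS1, first described in growth-arrested fibroblasts, at -1.76 ± 0.31. CDKN1A, the inhibitor p21, was at -0.11 ± 0.16 and did not pass (adjusted p = 0.245). The list was shifted downwards (camera adjusted p = 0.00262, and adjusted p = 0.471 with an estimated correlation). Among 21 target genes of p53, 11 were lower and 3 higher (11 and 4 adjusted over the list alone, 3 and 0 with the closest arrays averaged). They included TP53INP1 at -1.29 ± 0.36 and TP53I3 at -1.04 ± 0.42, both p53-induced, and CCNG1, a cyclin, at -1.03 ± 0.18. The p53 list passed narrowly (mean -0.27, camera adjusted p = 0.0435, and adjusted p = 0.471 with an estimated correlation) and did not pass without replicate 2 (adjusted p = 0.0509) or with the 6 arrays as separate replicates (adjusted p = 0.0512).

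Genes of epithelial junctions and desmosomes were more often lower than higher in the numerator culture. Of 14 measured genes of junctions and polarity, 9 were lower and 0 higher (9 and 0 adjusted over the list alone, 5 and 0 with the closest arrays averaged), with a mean of -0.52. JUP, the plaque protein plakoglobin, stood at -1.38 ± 0.33, CLDN1, a tight junction claudin, at -1.36 ± 1.13, CDH1, the adherens junction protein E-cadherin, at -0.93 ± 0.42, and SPINT1, a membrane inhibitor of proteases, at -0.81 ± 0.46. The clones of CDH1 did not behave alike, with means from -1.66 to 0.01, and the calls of CLDN1 and SPINT1 were lost with the closest arrays averaged (adjusted p = 0.109 and 0.0624). CLDN1 also missed the threshold without array 3. The list was shifted downwards (camera adjusted p = 0.00306, and adjusted p = 0.471 with an estimated correlation). In the list of desmosomes and hemidesmosomes 6 of 12 genes were lower and 2 higher (6 and 2 adjusted over the list alone, 5 and 0 with the closest arrays averaged). DSP, desmoplakin, at -1.60 ± 0.15, DST, which anchors keratin at hemidesmosomes, at -1.45 ± 0.32, and the desmosomal cadherin DSC3 at -1.29 ± 0.36 were among the lower genes. The higher genes were the desmosomal cadherins DSG2 at 0.35 and DSG1 at 0.21, named after their values were seen. That list, with a mean of -0.52, did not pass (camera adjusted p = 0.0767, and adjusted p = 0.524 with an estimated correlation), but did with the closest arrays averaged (adjusted p = 0.0393) and without replicate 1 or replicate 3 (adjusted p = 0.0423 and 0.0292). It also passed with the 6 arrays as separate replicates (adjusted p = 0.0476) and without arrays 1 and 3 (adjusted p = 0.0496).

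Differentiation markers of stratified and basal epithelium were also mostly lower. Of 13 keratinocyte differentiation genes, 9 were lower and 1 higher (10 and 2 adjusted over the list alone, 4 and 0 with the closest arrays averaged), with a mean of -0.58 (camera adjusted p = 0.00809, and adjusted p = 0.471 with an estimated correlation). Examples were SPRR1B and SPRR3, small proline-rich proteins of the cornified envelope, at -1.61 ± 0.38 and -1.27 ± 0.34, and S100A8, a calcium-binding protein of inflamed epithelium, at -1.60 ± 0.85. Of 9 basal and myoepithelial markers, 5 were lower and 0 higher (5 and 0 adjusted over the list alone, 2 and 0 with the closest arrays averaged), with a mean of -0.59 (camera adjusted p = 0.0176, and adjusted p = 0.471 with an estimated correlation). Besides MME, KRT14, a keratin of basal cells, was at -1.59 ± 0.15. CRYAB, a small heat shock protein, was at -0.48 ± 0.49 and lost its call on leaving out any array. Luminal breast markers went both ways, with 2 of 13 higher and 4 lower (2 and 4 adjusted over the list alone, 1 and 1 with the closest arrays averaged). Their mean was -0.17 and their median 0.004 (camera adjusted p = 0.714). KRT19, a keratin of luminal cells, was at -1.54 ± 0.42, while KRT7, another luminal keratin, was at 0.51 ± 0.16.

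EMT markers did not shift as a group. Of 22 measured mesenchymal and EMT markers, 6 were higher and 5 lower in the numerator culture (6 and 5 adjusted over the list alone, 0 and 1 with the closest arrays averaged). The list mean was 0.005, which changed sign when arrays were scaled or quantile normalized (camera adjusted p = 0.819). It was 0.205 on array 1 and 0.153 on array 3 but between -0.128 and -0.066 on the other 4, so opposite values cancelled in it. Without arrays 1 and 3 the mean was -0.077, with 7 genes higher and 7 lower (camera adjusted p = 0.714). ITGA5, the alpha chain of the fibronectin receptor, was at 0.60 ± 0.33, FN1, fibronectin, at 0.40 ± 0.13, and CDH2, N-cadherin, at 0.32 ± 0.18 (n = 5 arrays). These calls were lost with the closest arrays averaged (adjusted p = 0.0707, 0.0544 and 0.0752), those of FN1 and CDH2 also without replicate 3, and that of CDH2 without replicate 1. CALD1, which binds actin and tropomyosin, was lower at -1.21 ± 0.30. S100A4, a marker of fibroblasts, was at -0.81 ± 0.72 with 4 of 6 arrays negative, and TGFBI, a matrix protein induced by TGF-beta, at -0.39 ± 0.33, both losing the call with the closest arrays averaged (adjusted p = 0.149 and 0.137). S100A4 also lost it on leaving out array 2, 1R, 2R or 3R, and TGFBI on leaving out number 1 or 3 or array 2, 1R or 3R. SPARC, a matrix glycoprotein, did not pass at 0.19 ± 0.94 (adjusted p = 0.502) and was -0.40 without arrays 1 and 3 (adjusted p = 0.00344), its sign being negative on each of the other 4, but 0.52 without replicate 2 (adjusted p = 0.00233). The fit without replicate 2 averaged arrays of opposite sign within numbers 1 and 3.

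Transcription factors of EMT were divided as well. Of 8 measured, 2 were higher and 3 lower in the numerator culture (2 and 3 adjusted over the list alone, 1 and 3 with the closest arrays averaged; mean -0.24, camera adjusted p = 0.275). KLF8 stood at -0.99 ± 0.17, TWIST1 at -0.93 ± 0.22, and TCF3 at -0.87 ± 0.20, all known to repress E-cadherin or to act in its repression. The clones of TCF3 had means of -1.45 and 0.30. LEF1, a nuclear partner of beta-catenin, was higher at 0.72 ± 0.15. SNAI2, the repressor Slug, was at 0.47 ± 0.52 with 4 of 6 arrays positive, and its call was lost with the closest arrays averaged (adjusted p = 0.215) and on leaving out number 3 or array 2, 1R, 2R or 3R. SNAI1 at -0.08 ± 0.23 (adjusted p = 0.327) and ZEB1 at -0.11 ± 0.09 (adjusted p = 0.193) did not pass, though SNAI1 was -0.20 without arrays 1 and 3 (adjusted p = 0.0443). Of the other genes chosen for their link to EMT, CTNNB1, beta-catenin, at -0.14 ± 0.05 (adjusted p = 0.105) and EGFR, the receptor of epidermal growth factor, at -0.02 ± 0.35 (adjusted p = 0.862) did not pass. CTNNB1 was called with the 6 arrays as separate replicates (adjusted p = 0.0415), with the number as a random block (adjusted p = 0.0208) and with a channel term (adjusted p = 0.0451). EGFR was 0.23 without arrays 1 and 3 (adjusted p = 0.0264). CD44, the hyaluronan receptor, was at -0.24 ± 0.20 (adjusted p = 0.0407) and lost its call with the closest arrays averaged (adjusted p = 0.21), without arrays 1 and 3, and on leaving out number 1 or 3 or array 1, 2, 3 or 1R. Another 10 genes of this set, vimentin (VIM) among them, had no testable value here.

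Lists for density-linked and growth factor signalling did not pass as groups, though some members had large ratios. Of 20 target genes of YAP and TEAD, transcriptional regulators that respond to cell crowding, 9 were higher and 4 lower (10 and 5 adjusted over the list alone, 5 and 0 with the closest arrays averaged; mean 0.46, camera adjusted p = 0.158). After F3, the highest were NT5E, the ecto-nucleotidase CD73, at 2.06 ± 0.36, IGFBP3, a binding protein of insulin-like growth factors, at 1.44 ± 1.15, and ANKRD1, an ankyrin repeat protein, at 1.28 ± 0.31. IGFBP3 had 1 negative array and lost its call with the closest arrays averaged (adjusted p = 0.118) and on leaving out array 2, 1R, 2R or 3R. The classical targets CCN2 and CCN1, matricellular proteins, were at 0.62 ± 1.39 (adjusted p = 0.123) and -0.36 ± 0.62 (adjusted p = 0.0724), and the 2 clones of CCN1 differed in sign. CCN2 was 2.44 on array 1 and 2.39 on array 3 and negative on the other 4, against the sign of its mean, and CCN1 was positive on arrays 1 and 3 and negative on the other 4. Without arrays 1 and 3 CCN2 was -0.30 (adjusted p = 0.00963), and without replicate 2 it was 1.04 (adjusted p = 0.000469), so its direction depended on the arrays used. The fit without replicate 2 averaged arrays of opposite sign within numbers 1 and 3. CCN1 was -0.77 without arrays 1 and 3 (adjusted p = 0.000419) and was also called with arrays scaled (adjusted p = 0.0294) or quantile normalized (adjusted p = 0.0238). Of 23 genes responsive to TGF-beta, 8 were higher and 8 lower (9 and 8 adjusted over the list alone, 5 and 0 with the closest arrays averaged; mean 0.08, camera adjusted p = 0.748), with ID3, an inhibitor of DNA binding, at 0.97 ± 0.25, SMAD7, an inhibitor of the pathway, at 0.77 ± 0.23, and BHLHE40, a transcriptional repressor, at -0.78 ± 0.54. BHLHE40 lost its call with the closest arrays averaged (adjusted p = 0.0932).

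Immediate early genes differed between arrays. Of 20 measured, 5 were higher and 8 lower in the numerator culture (5 and 8 adjusted over the list alone, 3 and 6 with the closest arrays averaged; mean -0.26, camera adjusted p = 0.478). Besides FOS and EGR1, ATF3, a stress-induced factor, was lower at -1.43 ± 0.48, whereas PHLDA1, induced by growth factor signalling, was higher at 1.77 ± 0.32. The list mean was 0.14 on array 1 and 0.27 on array 3, and -0.57 to -0.52 on the other 4. Without arrays 1 and 3, left out after seeing the data, 4 genes were higher and 12 lower, the mean was -0.58, and the list passed (camera adjusted p = 0.0106).

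Inflammatory, interferon and ribosomal protein genes were more often lower than higher in the numerator culture. Of 28 inflammatory cytokines and NF-kappaB targets, 15 were lower and 2 higher (16 and 2 adjusted over the list alone, 7 and 1 with the closest arrays averaged; mean -0.49, camera adjusted p = 0.00809, and adjusted p = 0.471 with an estimated correlation). SOD2, the mitochondrial superoxide dismutase, stood at -2.30 ± 0.22, with clone means from -3.70 to -0.03, CXCL1, a chemokine that attracts neutrophils, at -2.09 ± 0.97, and TNFAIP3, a feedback inhibitor of NF-kappaB, at -1.49 ± 0.23. Of 41 genes of interferon response and antigen presentation, 20 were lower and 3 higher (22 and 4 adjusted over the list alone, 12 and 2 with the closest arrays averaged; mean -0.28, camera adjusted p = 0.00223, and adjusted p = 0.471 with an estimated correlation). HLA-E, a non-classical class I molecule, at -1.48 ± 0.67, IFI44, an interferon-induced protein, at -1.31 ± 0.49, and GBP2, a guanylate-binding protein, at -1.17 ± 0.42 were among them, and HLA clones cannot be assigned to a single HLA gene with certainty. Cytosolic ribosomal protein genes had 18 of 27 lower and 1 higher (21 and 1 adjusted over the list alone, 12 and 0 with the closest arrays averaged; mean -0.45, camera adjusted p = 3.67e-06, and adjusted p = 0.565 with an estimated correlation). RPL37 at -1.35 ± 0.48, RPL3 at -1.02 ± 0.40, and RPL31 at -0.93 ± 0.30 were among the lower genes, and clones of ribosomal proteins can also bind transcripts of processed pseudogenes.

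Adhesion, matrix and protease genes were split. Of 23 integrins and adhesion receptors, 6 were higher and 10 lower (6 and 10 adjusted over the list alone, 3 and 1 with the closest arrays averaged; mean -0.13, camera adjusted p = 0.481), with CD9, a tetraspanin, at -1.34 ± 0.16 and TLN1, which links integrins to actin, at 0.81 ± 0.38. Of 26 basement membrane and matrix genes, 5 were higher and 10 lower (5 and 10 adjusted over the list alone, 2 and 4 with the closest arrays averaged; mean -0.06, camera adjusted p = 0.394). The mean of that list was 0.07 on array 1 and 0.007 on array 3, and -0.107 without these arrays (camera adjusted p = 0.199). The laminin chains LAMB1 and LAMB2 stood at -1.24 ± 0.57 and -1.18 ± 0.18, and VCAN, the proteoglycan versican, at 1.61 ± 0.94, which lost its call with the closest arrays averaged (adjusted p = 0.0618). Extracellular proteases and inhibitors had 6 of 21 higher and 3 lower (6 and 3 adjusted over the list alone, 3 and 0 with the closest arrays averaged; mean 0.12, median -0.004, camera adjusted p = 0.748), with SERPINE2 above and MMP14, a membrane-bound metalloproteinase, at 1.20 ± 0.77, lost with the closest arrays averaged (adjusted p = 0.0523). The protease list had a mean of 0.013 on array 1 and -0.047 on array 3, and 0.20 without these arrays (camera adjusted p = 0.485). Of 23 genes of the actin cytoskeleton and motility, 7 were higher and 7 lower (7 and 7 adjusted over the list alone, 2 and 3 with the closest arrays averaged; mean -0.05, camera adjusted p = 0.748). MYH10, a non-muscle myosin heavy chain, was at -0.69 ± 0.24.

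Metabolic and stress lists held members on both sides and none passed as a group in the main camera test. By fry the cholesterol and sterol list alone among them passed (adjusted p = 0.0333). Cholesterol and sterol synthesis had 1 of 10 genes higher and 4 lower (1 and 7 adjusted over the list alone, 1 and 2 with the closest arrays averaged; mean -0.32, camera adjusted p = 0.0974), with INSIG1, which retains the sterol sensor, at -1.08 ± 0.11. This list passed without replicate 3 (adjusted p = 0.0395) and without arrays 1 and 3 (adjusted p = 0.0106). Glycolysis and hypoxia genes were divided 8 against 8 among 23 (9 and 8 adjusted over the list alone, 3 and 4 with the closest arrays averaged), with a mean of -0.02, a median of 0.09 and an upward test (camera adjusted p = 0.748). PGK1, phosphoglycerate kinase, was at 0.91 ± 0.25 and MXI1, an antagonist of MYC, at -1.07 ± 0.36. Mitochondrial respiratory chain genes had 4 of 21 higher and 8 lower (4 and 8 adjusted over the list alone, 2 and 2 with the closest arrays averaged; mean -0.06, camera adjusted p = 0.481). UQCRC1, of complex III, was at -0.94 ± 0.08 and CYCS, cytochrome c, at 0.86 ± 0.35. Without arrays 1 and 3 that list had 2 genes higher and 11 lower and passed (adjusted p = 0.0272). Heat shock and unfolded protein response genes had 10 of 22 higher and 4 lower (10 and 5 adjusted over the list alone, 5 and 2 with the closest arrays averaged; mean 0.20, camera adjusted p = 0.229). The mean of that list was 0.53 on array 1 and 0.50 on array 3 and between -0.07 and 0.11 on the other 4, and it was 0.04 with 7 genes higher and 7 lower when arrays 1 and 3 were left out. DNAJA1 at 1.01 ± 0.39 (n = 5 arrays) and HSPH1 at 0.84 ± 0.25, both cytosolic chaperones, were among the higher genes. Metallothioneins and oxidative stress genes had 7 of 16 higher and 4 lower (7 and 5 adjusted over the list alone, 2 and 2 with the closest arrays averaged; mean 0.17, median -0.03, camera adjusted p = 0.768), and leaving out arrays 1 and 3 gave a mean of 0.06 with 6 higher and 5 lower. MT2A, a metallothionein, was at 1.32 ± 0.59 and SRXN1, sulfiredoxin, at 0.99 ± 0.09, and metallothionein clones can bind several members of the family.

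Markers of other cell types did not shift as groups. Of 21 blood and immune markers, 2 were higher and 2 lower (2 and 1 adjusted over the list alone, 0 and 0 with the closest arrays averaged). The mean was -0.004 against an upward test, and it changed sign without centring (camera adjusted p = 0.975). Of 15 markers of endothelium, fat, muscle and nerve, 2 were higher and 4 lower (2 and 4 adjusted over the list alone, 1 and 1 with the closest arrays averaged; mean -0.11, camera adjusted p = 0.478), with TUBB3, a beta-tubulin of neurons, at 1.08 ± 0.24 and ENG, the TGF-beta coreceptor endoglin, at -1.02 ± 0.27.

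**Figure D3:**
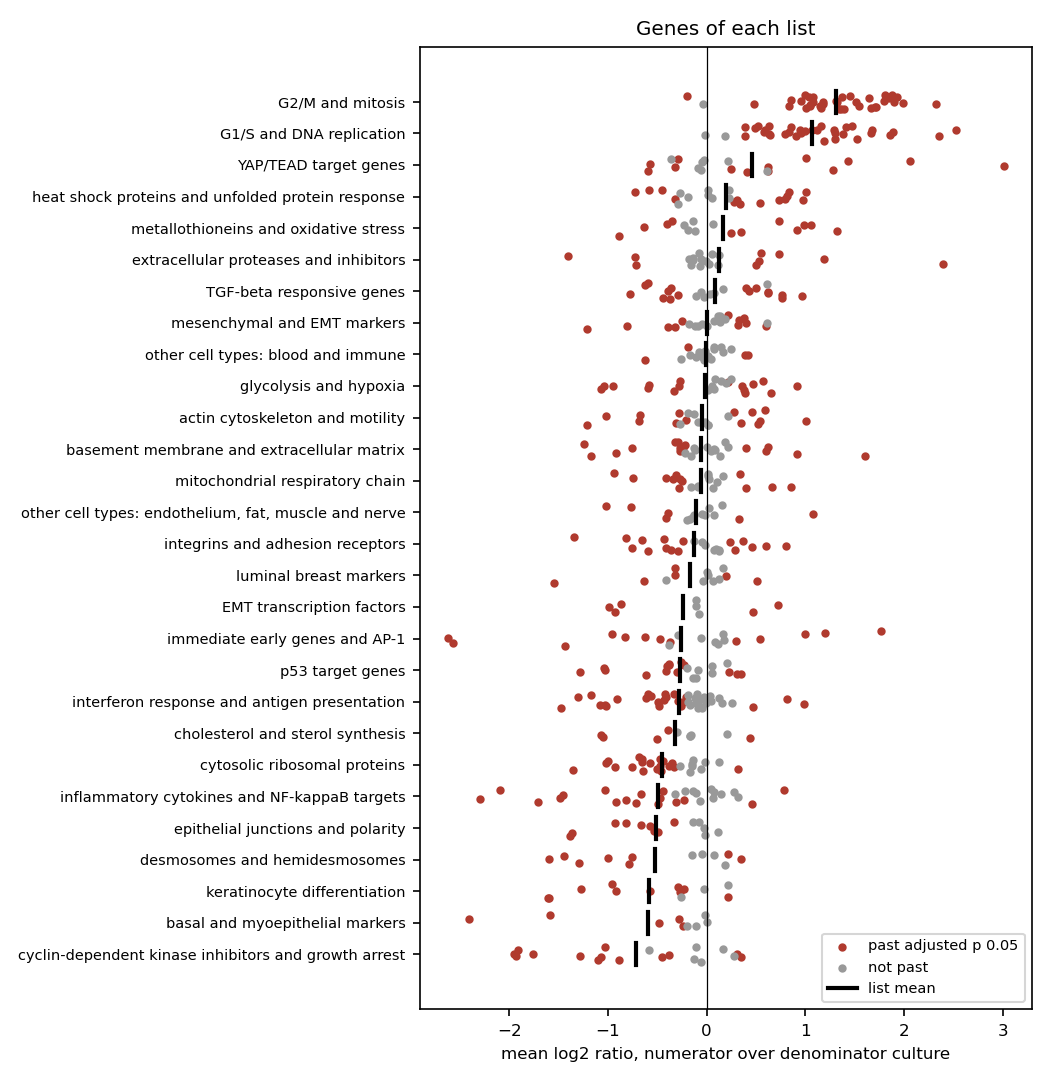
Mean log2 ratio of numerator over denominator culture for each measured gene of the 28 lists, with genes at an adjusted p under 0.05 in red, the others in grey and the list mean as a black bar. The G2/M and G1/S lists lie furthest to the right, with means of 1.31 and 1.07, and the growth arrest list furthest to the left, with a mean of -0.71.

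No gene was called for an effect of the channel that held a culture. Comparing arrays 1, 2 and 3 with arrays 1R, 2R and 3R called 0 of 5759 genes in limma, with 861 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.349. Arrays 1 and 3, which stood apart from the other 4, were on the same side of this comparison. The dyes themselves could not be tested in this way, because the confluent RNA was on Cy5 on 1 array alone. Which calls between the cultures a dye effect may have shaped is therefore unknown.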

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

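All tests on arrays 1 and 3 except that of slide position were chosen after the result was seen, and so was the count of other splits of the arrays.

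An array far from the others was seen for 10 of 163 results tested (named genes and list means over the arrays), where chance would give about 8.2 if arrays and results were independent. The arrays fall in close pairs, so that figure is only a guide. Arrays that deviate together, as arrays 1 and 3 did for CCN2, can go unflagged. AGAP1 was 7.90 on array 1 and between 2.11 and 3.26 on its other arrays. DSC2, a desmosomal cadherin, was -1.47 on array 1, below the other 5, which reached up to -0.73. GAS1 was -2.35 on array 1R against -1.82 to -1.51 elsewhere. LEF1 was 1.01 on array 2 against 0.59 to 0.71. TNNT1, a muscle troponin, was -0.84 on array 1 against -0.45 to -0.22. XBP1, a factor of the unfolded protein response, was -0.57 on array 2R against -0.29 to -0.24. The mean of the keratinocyte differentiation list was -0.70 on array 1 against -0.58 to -0.53, that of the growth arrest list -0.88 on array 1 against -0.73 to -0.65, and that of the integrins and adhesion receptors -0.21 on array 1 against -0.13 to -0.09. The mean of the inflammatory list was -0.36 on array 3 against -0.54 to -0.48. Signs were the same on every array in each of these cases.

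Arrays 1 and 3 stood apart from the other 4, with means of the cell-cycle lists further from 0 and a mean of the immediate early list that was positive there and negative on the other 4, although FOS, EGR1 and ATF3 were negative on every array. The means of the mesenchymal, mitochondrial, matrix and glycolysis lists changed sign between these groups of arrays in the same way. A common scale factor is argued against, since it leaves correlations as they are: the highest correlation of array 1 or 3 with the other 4 was 0.714, below the lowest among those 4, 0.828. Position on the slide is argued against too, as blocks of consecutive probes in the table, a stand-in for position, took 0.5% of the variance of the difference between the array groups. A different pair of cultures or RNA extracts for arrays 1 and 3 is a candidate explanation that cannot be told apart from a day or labelling effect, because the labels tie no array to a culture. There were 4 genes with opposite signs of at least 0.5 on both of these arrays against all of the other 4: DUSP6, a phosphatase that limits ERK signalling, JUN, a subunit of AP-1, IL22RA1, a cytokine receptor chain, and LRP1, an endocytic receptor, named after their values were seen.

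For the channel comparison, arrays 1, 2 and 3 against arrays 1R, 2R and 3R, limma called 0 genes (861 at an unadjusted p under 0.05), and the highest of the other splits of the arrays 3 against 3 also called 0. All 10 splits gave the same count. Unadjusted counts were 861 to 1095 in the 4 splits that kept arrays 1 and 3 together, the channel comparison among them, and 8 to 79 in the 6 that parted them, so they follow the structure of the arrays. With 10 splits no share under 0.05 can be reached.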

How the results depend on the processing

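The averages by closest pair, the closest pair as a random block and the fit without arrays 1 and 3 were chosen after the result was seen; all other alternatives were listed beforehand. The 2637 called genes became 1014 (585 higher, 429 lower) with the closest arrays averaged, and 1776 (980 higher, 796 lower) with the closest pair as a random block. A simulation without change that builds in deviations shared within these pairs raised unadjusted p-values under 0.05 to 18.8% of genes by number. It gave a mean of 0.6 adjusted calls by number and 0 by closest pair. With no gene changed, it does not give the false calls to be reckoned with where many genes pass, so the cause of the fall was not settled by it. As random blocks, the closest pair had a consensus correlation of 0.643 and the number one of -0.221. The pairs were chosen for their correlation. Averages by number thus split arrays that deviated together, and their standard errors may be too small. At 2-fold or more 324 genes remained (183 higher, 141 lower), by construction. Without moderation of the variance 0 genes were called, 0 higher and 0 lower (2408 at an unadjusted p under 0.05), with few degrees of freedom left. Reading the columns as channel 1 over channel 2 gave 0 genes (762 unadjusted) and as Cy5 over Cy3 0 genes (369 unadjusted) in limma. The former turns 1 array of each number, so their averages largely cancel by construction; named genes were not refitted under it, where the sign has no meaning. The latter turns array 1 alone, so the average of number 1 sets it against array 1R and partly cancels or changes sign. By construction this widens the spread between the averages, so the fall in calls is no separate evidence on the reading. Leaving out a number or an array gave 1444 to 2974 genes, 785 to 1500 higher and 659 to 1474 lower. The totals were 1613 without replicate 1, 2974 without replicate 2 and 1444 without replicate 3, each with 2 averages. Without replicate 2 both averages combined array 1 or array 3 with an R array. Averages so alike in make-up can differ little, so the higher count is no sign of firmer calls. The causes of these changes were not tested. All remaining counts, for the channel term, centring, scaling, quantile normalization, missing values, robust test, adjusted p under 0.10 and per probe, were within 1.5 times the main share or count. The count was 2657 without arrays 1 and 3, with 2187 of the 2637 genes among them.

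Same-numbered arrays did not deviate together (r of deviations -0.049, -0.031 and 0.002, and 0 of 6 arrays correlated best with their own number), so the numbers do not pair the arrays. With no replicate block, the 6 arrays as separate replicates, 2717 genes were called, and with the number as a random replicate block 3153.

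Without arrays 1 and 3, CCN2 turned to -0.30, EGFR to 0.23 and SPARC to -0.40, while without replicate 2 CCN2 was 1.04 and SPARC 0.52, both called. For CCN2 and SPARC, numbers 1 and 3 each average a positive array with a negative R array. These averages were nearly equal, 1.075 and 1.01 for CCN2 and 0.51 and 0.519 for SPARC, so the calls without replicate 2 settle no direction. Why arrays 1 and 3 differ was not settled. None of the 3 was called with all arrays. Of 127 called named genes, 106 kept the call on leaving out any number or array and 86 kept it with the closest arrays averaged. Fits without an array took single arrays as replicates, and with all 6 arrays taken so 123 kept the call. No named gene reversed under centring, scaling or quantile normalization, and 26 of 28 list means kept their sign there, the exceptions being the mesenchymal and the blood lists. Of 10 called lists 0 passed with an estimated correlation, which 3 averages estimate poorly, while fry called 19 lists as moving on balance in a direction and 28 as changed in either direction. The estimates were -0.0472, -0.0706, -0.0225 and 0.00142 for the junction, keratinocyte, interferon and growth arrest lists, below the preset 0.01. For the G1/S, G2/M and ribosomal lists they were 0.754, 0.784 and 0.342. A higher correlation thus does not account for the loss of the former. With an estimated correlation camera takes its degrees of freedom from the 3 averages, which leaves few. It could therefore hardly call any list, and the losses decide nothing about these lists. Signal over background could not be judged from ratios.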

Other observations

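The tests of the direction of the ratios were chosen after the result was seen; those on translation and other abundant transcripts were fixed before their medians were computed, though some of these transcripts belong to gene lists whose values had been seen.

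Other transcripts of the translation machinery lay on the same side as the ribosomal protein genes. Of 14 measured translation factors and related transcripts that share the 5' oligopyrimidine motif, 10 were lower and 1 higher in the numerator culture, with a median of -0.34 (95% bootstrap interval -0.62 to -0.18), beside a median of -0.47 (-0.64 to -0.27) for 27 ribosomal protein genes. The bootstrap drew genes as if independent and did not draw arrays. Its intervals thus leave out the spread between arrays and are too narrow where genes vary together. A bias shared by all abundant transcripts is argued against: 33 abundant transcripts outside translation, such as glycolytic enzymes and actins, had a median of 0.18 (0.01 to 0.44), with 15 higher and 6 lower. A shift of the whole translation machinery therefore stays open as a hypothesis. Whether binding of pseudogene transcripts contributes was not tested.

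The direction of the ratios stays open. Ratios left as Cy5 over Cy3 with the dyes as labelled are argued against by the positive correlations of array 1 with the other 5. The mean of the G2/M list would then have the opposite sign on array 1, and was 2.28 there and positive on all arrays. This sign follows from the correlations and is no separate test. The argument holds only if the dye label of array 1 is right. If sparse cultures cycle faster than confluent ones, which was not measured here, the numerator may be the sparse culture. That both cell-cycle lists had positive means and the growth arrest list a negative mean on 6 of 6 arrays is what prompted this hypothesis and is no test of it, and no label or value used here decides it. Under the hypothesis E-cadherin, plakoglobin and desmoplakin would be lower in sparse cells, and so would TWIST1 and KLF8.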
